A study of Mus musculus with 12 samples.

How the data were processed

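The data are 12 RNA-seq libraries from 1 mouse, a 14-month-old male hybrid of Castaneus and C57Bl6 (strain B6CASTF1/J per the labels). Per the labels, 13 Purkinje cells were excised from parasagittal tissue and homogenised together, and the pooled lysate was then divided so that each library received 1 cell-equivalent of total RNA longer than 200 bases together with spike-in RNA. The labels give all 12 libraries the same biological replicate number and technical replicate numbers 1 to 6 and 8 to 13, and libraries are named here by those numbers. There is 1 group, with no treatment and no control, so no group comparison was made. Every p-value below measures the technical spread among splits of 1 pool from 1 mouse, and nothing about variation between animals or between cells.

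Per the labels, the libraries were made with a Smart-seq protocol and the genome build was mm10. Per the text file deposited with each sample, the reads were quantified on mm10 with the GENCODE M4 annotation. The names of the aligner and of the quantification program are not given in the sources used here, and neither is the strand of the library. Per the file headers, the deposited gene and transcript tables hold expected counts, which are estimated read numbers in which reads shared between features are split and which are therefore not all whole. Per the file headers, the same tables hold TPM (length-scaled transcript shares) and FPKM (length-scaled fragment shares), which the authors computed with the spike-ins included, so that the TPM of all features in a library sum to the same total. The gene tables have 69691 features, of which 43346 are annotated genes, 96 are ERCC spike-ins, 1 is phiX and 26248 carry numeric identifiers. The numeric features were left out of all gene results because the tables do not name them. Gene symbols, types and coordinates came from GENCODE M21 on the same assembly, while the deposited tables use release M4; 42462 of the 43346 gene identifiers matched. All 258 genes of the fixed lists matched.

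Expected counts were rounded to whole numbers before the tests that need counts. A gene was called detected at an expected count of at least 1, and detection at 50 or more is given beside it. Detection against abundance was summarised by a binomial logistic fit of the number of detecting libraries on log2 mean TPM. Correlations between libraries were Spearman correlations of TPM across genes with a mean TPM of at least 1. Variation beyond Poisson sampling was tested per gene with a chi-square test of the counts against a common share of the gene totals, for genes with a mean count of at least 5. Variation beyond that of genes of similar abundance was tested in edgeR 4.0.16 on the same genes with TMM factors, an intercept-only quasi-likelihood fit (glmQLFit) and an upper-tail F test of each gene's quasi-dispersion against the abundance trend. Spike-ins and genes were compared by the difference in median log2 coefficient of variation (CV) from a running median over 501 genes of similar count, with a two-sided permutation test of 100000 resamples. Lists and pairs of related genes were compared within libraries on log2(TPM + 1) with the exact two-sided sign-flip permutation test over the 4096 sign patterns of the 12 libraries. Correlations over libraries are Pearson's r and Spearman's rho with two-sided permutation p-values, given again without the 2 libraries farthest from the median of the x axis and, with each block centred on its mean, within the blocks of replicate numbers 1 to 5, 6 to 10 and 11 to 13. These blocks were chosen after the correlations between libraries were seen, and none holds enough libraries for an r of its own. All families of tests were adjusted by the Benjamini-Hochberg method at 0.05. Co-variation within a list is the mean Spearman correlation over its gene pairs with a mean TPM of at least 1, placed as a percentile among 10000 random lists matched on mean TPM. Leading transcripts were compared for genes with a mean TPM of at least 10 and at least 2 annotated transcripts. Intervals for shares are 95% Wilson intervals, and the limit set by a count of 0 is 3 counts of the library's gene total. The reads come from PCR without molecular identifiers, so intervals and limits cover counting error only.

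The gene lists, the pairs, the tests of lists, pairs, variation, detection and co-variation with their thresholds, the alternatives marked as planned and the rule for naming genes were fixed before the data were examined. The relations with replicate number and with gene counts per spike-in count were chosen after. The naming rule took the 4 members with the highest mean TPM and the measured member with the lowest from each list, every pair discussed, the 10 nuclear-encoded genes with the highest mean TPM, the 10 genes with the smallest adjusted p for variation beyond the abundance trend, and all Y-linked and X-inactivation members. Some genes that the rule takes, and pairs that hold them, are not reported here one by one; they stay in the list sums, the tests and the adjustment for multiple tests. The 26 lists were those for Purkinje cells, granule cells, inhibitory interneurons, Bergmann glia and astrocytes, oligodendrocytes, microglia, endothelial and mural cells, choroid plexus and ependyma, and red blood cells; zebrin-positive and zebrin-negative Purkinje cells; immediate early and heat shock genes; sodium, calcium, and potassium and HCN channels; glutamate and GABA receptors; GABA synthesis and transport; calcium handling; the cytoskeleton; the nuclear and the mitochondrially encoded respiratory chain; inherited ataxias; and Y-linked and X-inactivation genes.

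Total expected counts ran from 15167444 to 27806010 per library, and the gene counts alone from 13694551 to 24108916, so that a count of 0 allows at most 0.124 to 0.219 CPM (counts scaled to the gene total) in a single library and 0.0137 over all 12. Each pair of libraries was checked for duplicated files with the chi-square per gene between them, which was 560.1 for the closest pair, libraries 4 and 13, so no pair was alike within sampling noise. The steps were tested on simulated data with the real means, and for the Poisson and edgeR tests also with the real depths. The Poisson test recovered 90.5% of 200 genes given an extra dispersion of 0.1, with 5 false calls. The logistic fit returned 3.00 where 3 was put in, on data drawn from the same logistic form that was fitted. The list percentile passed 95 in 97% of simulated lists with a shared factor of SD 0.5 and in 1% of lists with none. That simulation gave every gene the same relative spread and no value of 0, unlike the real genes. It therefore cannot give the power of the percentile in these data. The edgeR test recovered 13.5% of 200 genes given 4-fold the trend's dispersion and 18.5% of those given 16-fold, and among the 577 genes with a mean count of at least 5000 it recovered 36% and 77%. It made 6 to 8 false calls in those simulations and 3 where no change was put in. The alternatives changed the filter, pseudocount, unit, depth, normalisation (DESeq2 1.42.0 size factors), tool (scran 1.30.0) or detection threshold 1 at a time, or left out each library in turn. Others, chosen after seeing the data, left out libraries 1, 4 and 13 together, set counts under 50 to 0, raised a threshold or matched spike-ins on TPM. Tools were R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.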

Results

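Total RNA longer than 200 bases was measured by Smart-seq in 12 libraries, each made from 1 cell-equivalent of a homogenate of 13 Purkinje cells from 1 male mouse. Purkinje cells are the large inhibitory neurons that carry the output of the cerebellar cortex. Because the lysate was pooled before it was divided, the libraries form 1 group and differ in sampling and handling, not in the cells they came from. The total expected counts averaged 20509107 ± 4364356 per library (SD, n = 12), from 15167444 in library 5 to 27806010 in library 10. Annotated genes numbered 9680 ± 1037 per library at an expected count of at least 1 and 6465 ± 1079 at a count of at least 50. Mitochondrially encoded genes held 3.86 ± 0.949% of the gene counts.

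Several genes used to mark Purkinje cells, Pcp4, Pcp2 and Gng13 among them, were abundant in every library. Pcp4 (ENSMUSG00000090223.1; mm10 chromosome 16, 96467606 to 96525793), which encodes a small calmodulin-binding peptide, stood at 7724 ± 1814 TPM (SD, n = 12). Pcp2 (ENSMUSG00000004630.14; chromosome 8, 3623371 to 3625545), a regulator of G protein signalling used to mark Purkinje cells, stood at 7156 ± 1529 TPM. Gng13, a G protein gamma subunit, stood at 5459 ± 1372 TPM, and Calb1 (ENSMUSG00000028222.2; chromosome 4, 15881264 to 15908064), the calcium buffer calbindin, at 1597 ± 357 TPM. Of the 20 genes in the Purkinje list, 19 had a mean TPM of at least 1, 18 had a count in every library, and 14 had at least 50 counts in every library. The exception below 1 TPM was Skor2, a transcriptional corepressor of Purkinje cell development, with counts in 3 libraries and a mean of 0.757 ± 1.84 TPM. The list summed to 26449 ± 5040 TPM, from 19662 in library 4 to 34488 in library 8.

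Genes of the other cerebellar cell types were lower, by very different amounts. Bergmann glia, the astrocytes that wrap Purkinje cell dendrites, came closest: Slc1a3, the glial glutamate transporter GLAST, stood at 882 ± 429 TPM (SD, n = 12), Hopx at 396 ± 128, Timp4 at 393 ± 232 and Gja1, the gap junction protein connexin 43, at 338 ± 177. Gfap, an intermediate filament of astrocytes and a member of the same list, went the other way, averaging 1.27 ± 4.13 TPM and reaching 50 counts in 1 library. Haemoglobin transcripts were also present in every library, with Hba-a1 at 285 ± 134 TPM, Hbb-bs at 284 ± 139.6 and Hba-a2 at 163 ± 127, whereas Hbb-bt stood at 12.7 ± 25.2 and Alas2, the erythroid enzyme of haem synthesis, had counts in 1 library (0.102 ± 0.352 TPM). The 2 alpha globin genes are nearly alike in sequence, as are the beta globin genes, so the division of reads between members of a pair is uncertain.

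Granule cell genes formed an intermediate group. Gabra6, the GABA receptor subunit typical of granule cells, stood at 99.2 ± 66.4 TPM, Calb2 (calretinin) at 94.7 ± 68.0, Chn2 at 89.0 ± 62.4 and the transcription factor Neurod1 at 73.3 ± 52.3 TPM (SD, n = 12), while Zic2 averaged 1.22 ± 2.50. Oligodendrocyte genes were lower again, with Cnp at 70.3 ± 49.9 TPM, the myelin genes Mbp at 65.3 ± 83.3 and Mobp at 9.78 ± 19.8, and Mog, a late myelin gene, at 0.313 ± 1.05. Genes of the inhibitory interneuron list were found in some libraries and not in others. Lgi2 averaged 16.5 ± 29.6 TPM, with 50 or more counts in 4 libraries, Kit 6.73 ± 9.16 in 5, Tfap2b 5.80 ± 13.4 in 4 and Cdh22 4.13 ± 6.18 in 6. Sst, the peptide somatostatin, had no count in any library, which allows at most 0.0137 CPM (counts scaled to the gene total) over all 12. This limit covers counting error only, so RNA that was not captured could lie above it.

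Microglial and vascular genes appeared in a few libraries at a time. Ctss, a lysosomal protease of microglia, averaged 49.0 ± 93.6 TPM, with 50 or more counts in 4 libraries, Tyrobp 32.8 ± 77.1 in 2 and C1qb 19.7 ± 37.6 in 3 (SD, n = 12), and Fcer1g had no count. Among vascular genes, Ly6c1 averaged 12.0 ± 30.4 TPM with 50 or more counts in 2 libraries, Vtn 8.45 ± 29.1 in 1, Rgs5 6.84 ± 23.3 in 2 and Flt1, a VEGF receptor, 1.96 ± 5.21 in 2, and the smooth muscle actin Acta2 had no count. Of the 8 choroid plexus and ependyma genes, 6 had no count in any library, among them Ttr, the transthyretin of choroid plexus, and Folr1; Clic6 averaged 4.37 ± 11.5 TPM and Foxj1 0.111 ± 0.296.

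**Figure D1:**
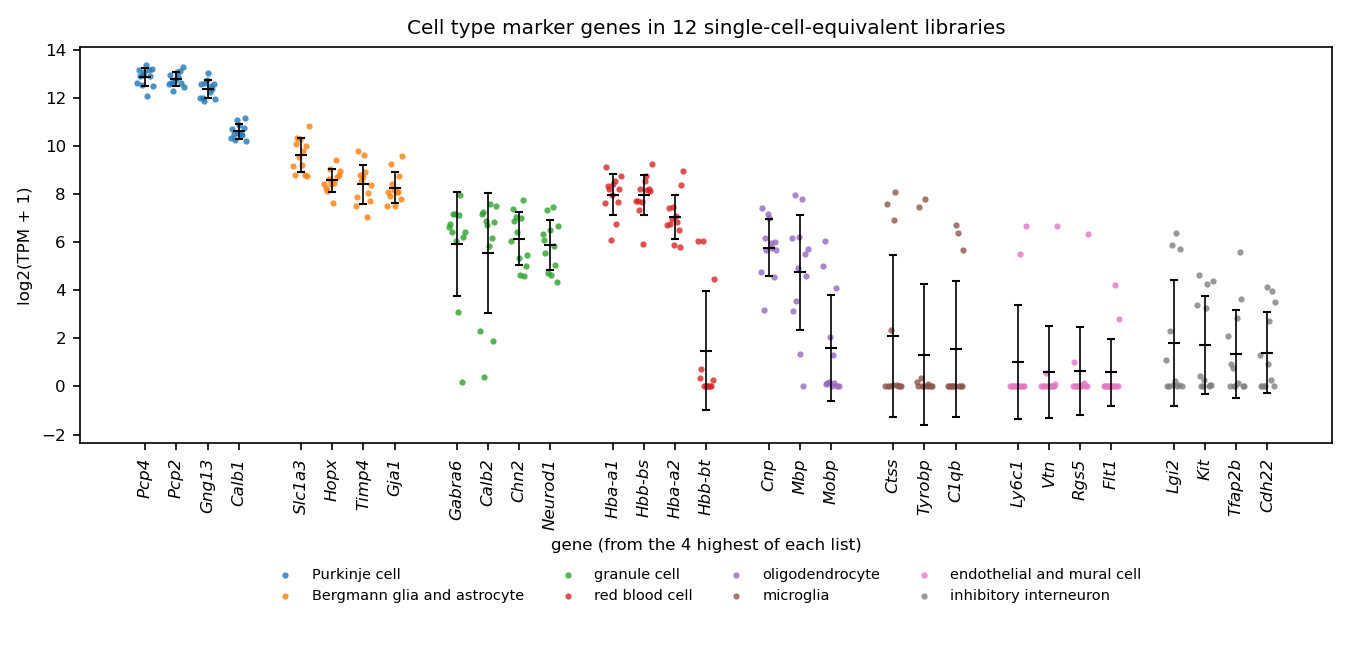
Expression on the log2(TPM + 1) scale of genes from the 4 highest of each cell type list except choroid plexus, with 1 point per library (n = 12) and bars for the mean and SD. Purkinje genes such as Pcp2 (7156 ± 1529 TPM, SD) lie at the top in every library, as do Pcp4 and Gng13, Bergmann glia and globin genes are lower except that Slc1a3 exceeded Calb1 in libraries 4 and 13, and microglial and vascular genes are at 0 in most libraries.

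Compared within each library, the median log2(TPM + 1) of each of the 8 other cell type lists was below that of the Purkinje list, which was 8.19 ± 0.23 (SD, n = 12). The difference was smallest for red blood cells (−1.28 ± 0.91, lower in 11 of 12 libraries, adjusted p = 0.00195) and for Bergmann glia and astrocytes (−1.35 ± 0.73). It was −4.10 ± 1.12 for granule cells, −7.71 ± 1.15 for oligodendrocytes, −7.97 ± 0.78 for microglia, −8.03 ± 0.69 for endothelial and mural cells, −8.14 ± 0.29 for interneurons and −8.19 ± 0.23 for choroid plexus. The Bergmann list and these lists, 7 in all, were lower in 12 of 12 libraries. Each had an unadjusted p of 0.000488, the smallest the exact sign-flip permutation test can give with 12 libraries, and an adjusted p of 0.000558. The list medians averaged 0.48 for oligodendrocytes, 0.22 for microglia, 0.16 for endothelial and mural cells, 0.051 for interneurons and 0 for choroid plexus. They lie at or near the floor of the scale, so these differences mostly restate the Purkinje median and their order carries little information. The Bergmann list summed to 2829 ± 859.6 TPM, the granule list to 507 ± 234 and the microglial list to 134 ± 171.

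Calcium handling was the most abundant of the neuronal function lists, at 18168 ± 3507 TPM in sum (SD, n = 12). Calm2, which encodes calmodulin, stood at 6804 ± 1539 TPM, and the calcium buffer parvalbumin (Pvalb) at 3635 ± 947. The lowest member, the ryanodine receptor Ryr1, averaged 4.06 ± 4.81 TPM. Energy metabolism was similarly high: the nuclear respiratory chain list summed to 15759 ± 1900.4 TPM, with Ndufa4 at 3220.1 ± 726, Atp5b at 2581 ± 927, Cox6c at 1708 ± 468 and Uqcrb at 1504 ± 321, and its lowest member, cytochrome c (Cycs), at 169 ± 48.9. The mitochondrially encoded list summed to 43940 ± 12793 TPM, with mt-Atp8 at 8119 ± 3083, mt-Atp6 at 7005 ± 2063, mt-Cytb at 6128 ± 2257 and mt-Nd1 at 5922 ± 1492, and mt-Nd4l, the lowest, at 56.6 ± 40.9.

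The glutamate receptor list summed to 763 ± 165 TPM (SD, n = 12). It held the AMPA subunits Gria2 at 109 ± 59.0 TPM and Gria4 at 80.3 ± 39.6, while Grm5, a metabotropic receptor, averaged 0.742 ± 1.74. The GABA receptor list summed to 578 ± 116 TPM. It held Gabra6, given above, and Gabrd at 36.5 ± 38.7 TPM, and Gabra5 had no count. Gabra6 and Gabrd are known from granule cells, and Gabra6 is also in the granule list. The GABA-synthesising enzyme Gad1 stood at 406 ± 165 TPM, Gad2 at 49.4 ± 31.8, Abat at 46.6 ± 22.8 and the vesicular transporter Slc32a1 at 16.9 ± 12.9. All 5 genes of that list had at least 50 counts in every library, against 8 of the 14 glutamate receptor genes and 2 of the 11 GABA receptor genes.

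Ion channel genes were far less abundant than the calcium buffers Calb1 and Pvalb, though not than the buffer Calb2. In the sodium channel list, Scn1a stood at 67.7 ± 36.9 TPM, Scn2b at 52.4 ± 27.5 and Scn8a at 37.9 ± 11.8 (SD, n = 12), and Scn3a averaged 0.0292 ± 0.0794. The calcium channel list was led by the beta subunit Cacnb4 at 68.2 ± 38.6 TPM and by Cacna1a, the P/Q-type pore, at 40.5 ± 39.2, followed by Cacna1g (23.8 ± 12.4) and Cacna2d2 (20.2 ± 23.8); Cacna1b averaged 0.101 ± 0.282. In the potassium channel list, Kcnip1 stood at 268 ± 173 TPM, Kcnma1, the BK channel, at 101 ± 55.9 and Kcna1 at 49.9 ± 28.1, and Hcn2 averaged 0.416 ± 1.01.

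The inherited ataxia list summed to 1483 ± 276 TPM (SD, n = 12). Itpr1, the IP3 receptor through which calcium leaves internal stores, stood at 416 ± 64.9 TPM and Atxn10 at 172 ± 74.9, while Atxn3 had counts in 2 libraries (0.304 ± 0.726 TPM). Of the 17 ataxia genes, 15 had a mean TPM of at least 1. In the cytoskeleton list, Stmn3 stood at 1039 ± 303 TPM, Dynll1, a dynein light chain, at 622 ± 366, Stmn2 at 452 ± 158 and Tuba1a at 364 ± 199, and the lowest, Map1a, at 11.8 ± 8.62.

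Genes of the lists for both kinds of Purkinje cell stripe had counts in the pool. The pool also held Bergmann glia transcripts, and which cells each of these RNAs came from was not tested. Aldoc, the enzyme that is the zebrin antigen, stood at 1959 ± 464 TPM (SD, n = 12), but the other zebrin-positive genes were much lower, with Gabbr2 at 65.1 ± 30.8, Slc1a6 at 49.3 ± 50.8, Kctd12 at 6.29 ± 9.98 and Hspb1 without a count in any library. The zebrin-negative list held Plcb4 at 319.8 ± 70.2 TPM, Ncald at 37.1 ± 63.9 and Ebf2 at 34.2 ± 24.8.

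Immediate early genes, which neurons induce on stimulation, were found in a few libraries at a time, with a summed level of 24.9 ± 26.8 TPM over 13 genes (SD, n = 12). Dusp1 averaged 8.05 ± 14.4 TPM, with 50 or more counts in 5 libraries and 49.0 TPM in library 6, Btg2 averaged 6.06 ± 9.12 with such counts in 4, Jun 2.83 ± 4.44 in 4 and Fos 2.49 ± 8.54 in 1, where it stood at 29.6 TPM. Of the list, 4 members had no count in any library, Atf3 among them, and none had a count in all 12. The chaperones Hspa8, Hsp90aa1 and Hsp90ab1 stood at 1108 ± 483, 1077 ± 318 and 1041 ± 354 TPM and the endoplasmic reticulum chaperone Hspa5 at 167 ± 90.3. Of the 9 genes of the heat shock list, 5 had 50 or more counts in every library and 2, Hspb1 among them, had no count. Of the Y-linked genes, Ddx3y stood at 45.7 ± 40.7 TPM, Eif2s3y at 45.6 ± 42.5, Uty at 6.18 ± 18.1 and Kdm5d at 0.248 ± 0.845. Xist, the RNA that silences 1 X chromosome in females, had counts in 1 library (0.0408 ± 0.141 TPM), and the gene on the other strand, Tsix, had none; without the strand of the library these 2 cannot be separated.

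Pairs of related genes showed strong preferences for 1 member. The IP3 receptor Itpr1 exceeded Itpr2 (1.44 ± 4.61 TPM) by a log2 ratio of 8.25 ± 1.27 (SD, n = 12). It also exceeded Itpr3, which had no count in any library and so lay at or below 0.0137 CPM. The phospholipase Plcb4 exceeded Plcb3 by 7.41 ± 1.55, the nuclear receptor Rora exceeded Rorb by 6.38 ± 1.64, and the scaffold protein gene Homer3 exceeded Homer1 by 6.00 ± 2.65. All of these held in 12 of 12 libraries (adjusted p = 0.00076 in the exact sign-flip permutation test, whose unadjusted p of 0.000488 is the smallest it can give).

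Smaller differences held as well. At the same adjusted p and in 12 of 12 libraries, Calb1 exceeded Calb2 by 5.06 ± 2.43, Kcna1 exceeded Kcna2 by 4.79 ± 0.97, Camk2b exceeded Camk2a by 4.34 ± 1.99, Atp2b2 exceeded Atp2b1 by 3.98 ± 1.48, Gad1 exceeded Gad2 by 3.21 ± 0.95 and Aldoc exceeded Aldoa by 0.56 ± 0.33 on the log2 scale (SD, n = 12). Slc1a6, the Purkinje glutamate transporter, was below the glial Slc1a3 in 12 of 12 libraries, with a log2 ratio of −5.01 ± 2.32. Scn8a exceeded Scn2a by 1.51 ± 1.33 in 11 libraries (adjusted p = 0.00432), and Gria3 was below Gria2 in 10 libraries (−1.10 ± 1.65, adjusted p = 0.0176), a call that ended without libraries 1, 4 and 13 (−1.25, adjusted p = 0.0573).

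In all, 21 of 28 pairs differed, and of the 18 reported one by one, 14 did. The 4 of these that did not pass were Gria1 against Gria2 (−0.49 ± 1.28, adjusted p = 0.250), Scn8a against Scn1a (−0.61 ± 1.35, 0.183), Cacna1a against Cacna1g (0.13 ± 1.77, 0.808) and Nefm against Nefl (−0.13 ± 1.72, 0.808), all by the exact sign-flip permutation test (SD, n = 12). Without library 11, Scn8a against Scn1a passed (−0.92, adjusted p = 0.0087). As CPM, which does not correct for transcript length, Cacna1a was below Cacna1g and the pair passed (−1.29, adjusted p = 0.00456). The sign turned for Cacna1a against Cacna1g without library 1 (−0.061), 3 (−0.000944) or 8 (−0.17) and for Nefm against Nefl without library 1 (0.13) or 13 (0.11).

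**Figure D2:**
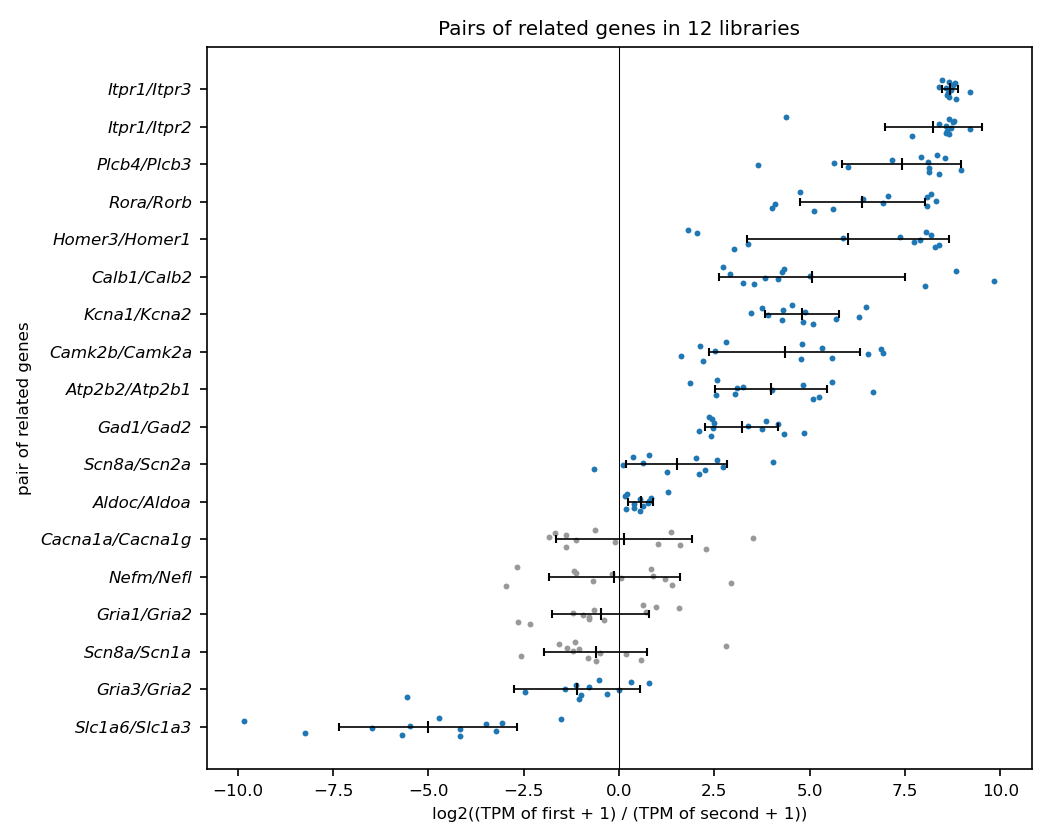
Log2 ratio of TPM + 1 between the members of 18 pairs of related genes, with 1 point per library (n = 12), blue where the pair passed the test and grey where it did not, and bars for the mean and SD. Pairs such as Itpr1 against Itpr2 (8.25 ± 1.27, SD) lie on 1 side of 0 in every library, while Cacna1a against Cacna1g (0.13 ± 1.77) and Nefm against Nefl (−0.13 ± 1.72) spread over both sides.

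The 10 nuclear-encoded genes with the highest mean TPM combined Purkinje genes with RNAs that share reads. Malat1 (ENSMUSG00000092341.2, chromosome 19 from 5795690), a long noncoding RNA kept in the nucleus, stood at 56639 ± 48236 TPM and Gm37376 (ENSMUSG00000102349.1, from 5801941), which overlaps it, at 43761 ± 37276 (SD, n = 12). Because these overlap, the division of reads between them is uncertain. Gm28437 (13200.4 ± 5176 TPM), Gm29216 (10721 ± 2846), Gm10925 (10510 ± 4343) and Gm28661 (8519 ± 3692) are copies of mitochondrial sequence that lie side by side on chromosome 1 between 24613189 and 24615706 at their starts, so the division of reads between them and the mitochondrial genes is uncertain. The rest were Pcp4, Pcp2, Calm2 and Actb, the cytoskeletal actin, at 5806 ± 793 TPM.

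How closely splits of 1 homogenate matched depended on abundance. Of genes with a mean TPM of at least 1000, 100% had 50 or more counts in every library, and of those from 100 to 1000 TPM, 72.1%. The share fell to 13.7% of the 5385 genes from 10 to 100 TPM and to 0.372% of the 5650 genes from 1 to 10 TPM. The median CV was 0.280 above 1000 TPM, 0.602 from 100 to 1000, 1.30 from 10 to 100 and 2.28 from 1 to 10. In all, 3667 genes had a count of at least 1 in every library, while 26412 had a count of at least 1 in none. At a threshold of 50 counts, chosen after seeing the data, 1613 genes were detected in every library, which is less than the count at a threshold of 1 by over 1.5 times; at 5 counts there were 2364 and at 1 TPM 1704.

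The abundance at which a gene was detected in 6 of the 12 libraries was 0.79 on the log2 TPM scale, with an SD of 1.03 between the fits of single libraries (n = 12). At a count of at least 5 it was 2.53, and at 50 it was 3.46. The median Spearman correlation between 2 libraries was 0.503 (range 0.467 to 0.562 over 66 pairs), across genes with a mean TPM of at least 1; genes are not independent replicates. The median moved by more than the SD between pairs (0.0212) under several alternatives, from 0.451 at a mean of at least 10 TPM to 0.578 at 100 TPM. With 1 library left out it stayed within that SD. Libraries with nearby technical replicate numbers correlated more closely, a relation tested after seeing the data, with a mean of 0.525 over the 10 pairs of neighbouring numbers and means of 0.487 to 0.501 at each difference from 5 to 11, but 0.520 in the only pair that differed by 12, libraries 1 and 13. Over all pairs, rho between the correlation and the difference in number was −0.507 (permutation p = 0.0011 over 10000 relabellings, two-sided), and with counts under 50 set to 0, chosen after seeing the data, it was 0.0186 (p = 0.883).

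**Figure D3:**
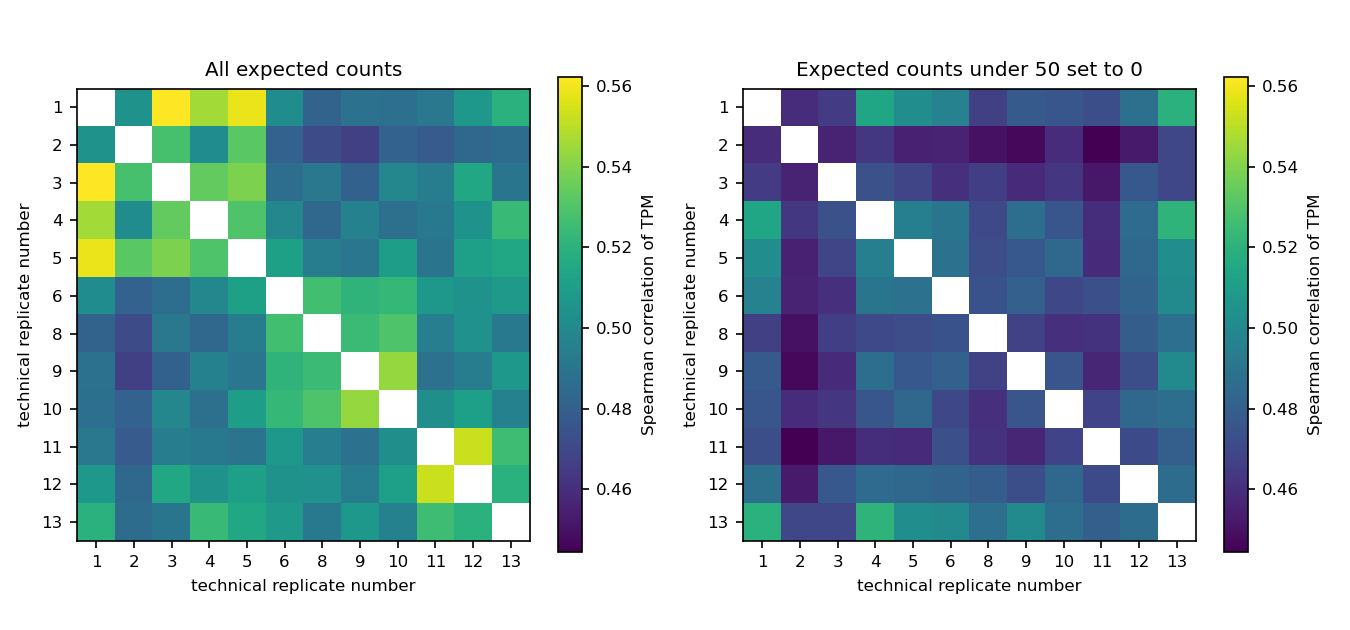
Spearman correlation of TPM between each pair of the 12 libraries, ordered by technical replicate number on both axes, with all counts kept and with counts under 50 set to 0. The pair values with all counts kept run from 0.467 to 0.562, with higher values near the diagonal, while with counts under 50 set to 0 the correlation with the difference in number is 0.0186.

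**Figure D4:**
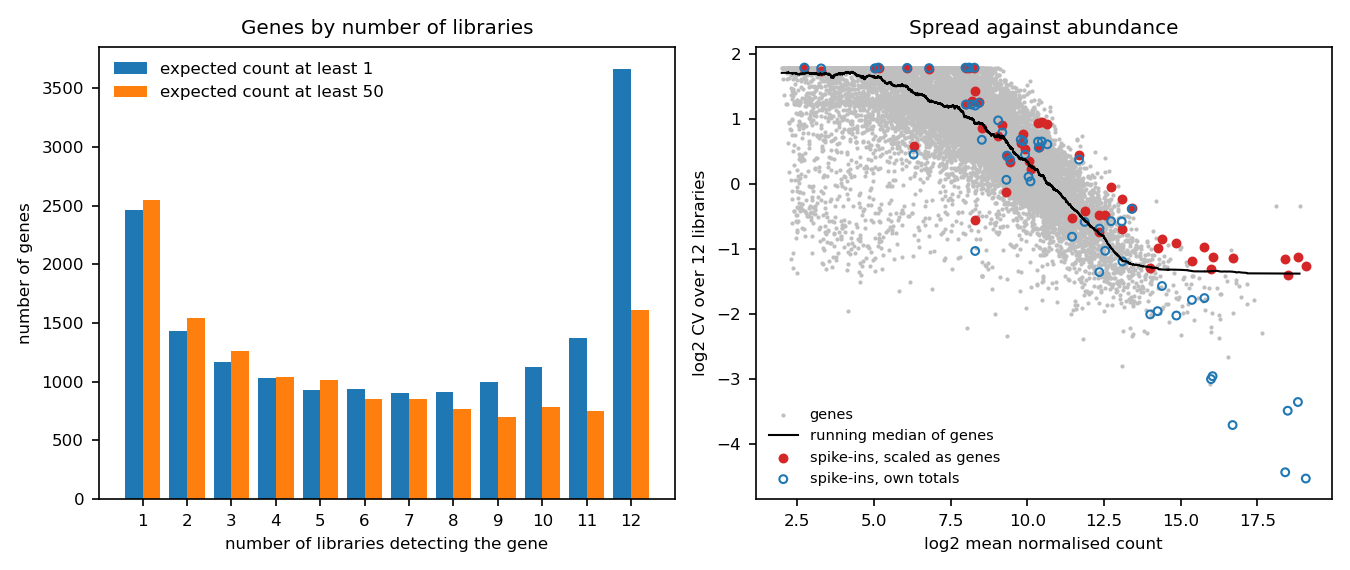
Left, the number of genes (bars) detected in 1 to 12 libraries at an expected count of at least 1 or at least 50, where 3667 and 1613 genes were found in all 12. Right, log2 CV over the 12 libraries against log2 mean normalised count for genes (grey points, with their running median as a line), for ERCC spike-ins scaled as genes and for spike-ins scaled by their own totals, which lie lowest at high counts.

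Nearly every gene varied more than Poisson sampling of reads allows. Of 13899 genes with a mean count of at least 5, 13889 did so (chi-square, adjusted p under the 0.05 threshold), and the pattern held after thinning to a hundredth of the shallowest library (4917 of 4933 genes). Beyond the abundance trend, edgeR called 2 of 13899 genes, Malat1 (adjusted p = 0.0001399) and its overlapping neighbour Gm37376 (adjusted p = 0.001305), and 95 had an unadjusted p under 0.05. In data simulated with no change put in, the same test called 3 of 13899 genes, all false, so a count of 2 was no larger than in that simulation. However, 3.52% of unchanged simulated genes had an unadjusted p under 0.05, against 0.68% of the real genes. The simulation therefore did not match the data in this, and it cannot decide whether the 2 calls were errors. Malat1 ran from 18842 TPM in library 12 to 191848 in library 1. The next genes did not pass: ENSMUSG00000045999.9, which has no symbol in the annotation used, had an adjusted p of 0.260, and Gm42418, Ubb (polyubiquitin), Gm28437, mt-Cytb, Gm10925, Calb1 and Calm2 each had 0.773. Both calls depended on the tool: scran called 270 genes (725 at an unadjusted p under 0.05), neither Malat1 nor Gm37376 among them, and the robust edgeR fit called 0. ENSMUSG00000045999.9 passed with scran (adjusted p = 1.42e-05), and with counts under 50 set to 0, chosen after seeing the data, it passed together with Gm42418, Gm28437, mt-Cytb and Gm10925. Without library 1 edgeR called 1 gene, as Gm37376 no longer passed (adjusted p = 0.0706), and without libraries 1, 4 and 13 it called 0.

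Spike-in RNA, which was added to the libraries and so never passed through the cells, varied slightly more than genes of similar count. The 53 ERCC species with enough counts lay 0.23 above the genes' running median on the log2 CV scale, 42 of them above it (permutation p = 0.00261, two-sided). Features are not independent replicates. Scaling the spike-ins by their own totals ended the difference (0.070, p = 0.333), as did leaving out library 13 (0.14, p = 0.0542) or libraries 1, 4 and 13 together (0.071, p = 0.325). Matched on mean TPM in place of count, chosen after seeing the data, the difference was 0.50 (p = 1e-05, the smallest the permutations can give). For species with at least 50000 counts, the median CV was 0.454 on the genes' scale and 0.0939 on their own, against 0.306 for the 32 genes of that abundance. These species hold most of the spike-in counts, so scaling by the spike-in total itself lowers their CV, and 0.0939 is not comparable with the genes' value.

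The amount of gene signal per spike-in set libraries 1, 4 and 13 apart. They held 15.3 to 19.9 gene counts per spike-in count, against 5.86 to 9.83 in the other 9, and spike-ins made up 4.78% of the counts of library 13 (95% interval 4.77 to 4.79%) and 14.6% of those of library 3 (14.6 to 14.6%). The same 3 libraries had the most genes at 50 or more counts, 7775 to 8645 against 5407 to 6772 in the others. They were also the 3 libraries with the highest Malat1, at 191848, 84919 and 80650 TPM. Mitochondrially encoded genes held 4.08, 5.74 and 5.49% of their gene counts, against 2.56 to 4.18% in the other 9. Library 1 thus did not stand apart in this share of the gene counts. However, Malat1 and Gm37376 held 94892 and 55309 CPM in library 1, against at most 39159 and 24291 in any other library. Their large part lowers every other share of library 1.

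**Figure D5:**
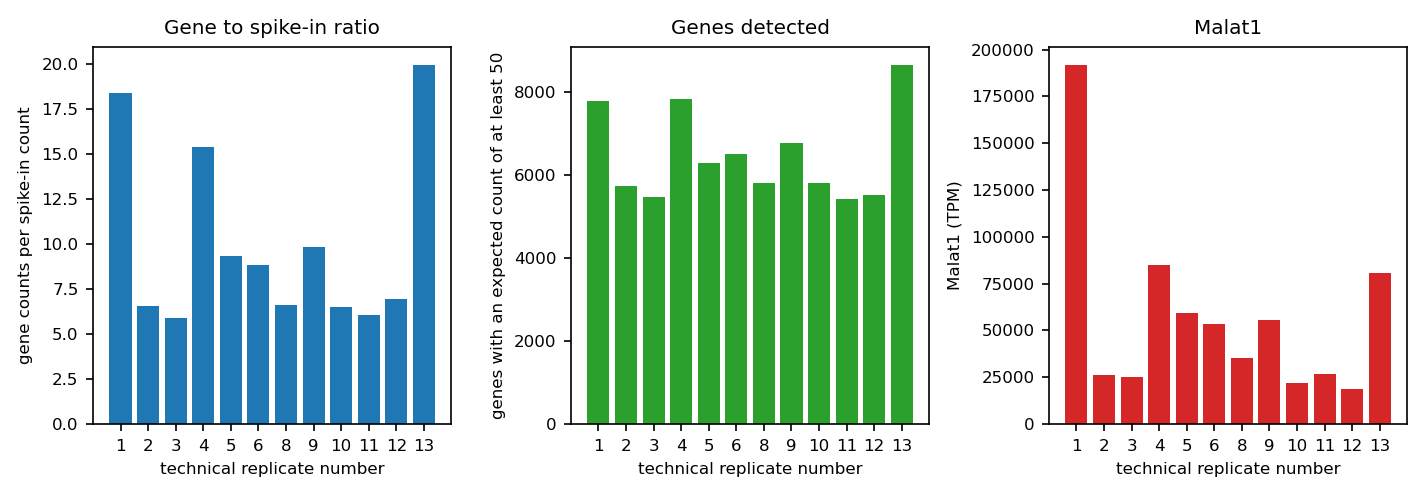
Gene counts per spike-in count, genes with an expected count of at least 50, and Malat1 TPM, each as 1 bar per library by technical replicate number. Libraries 1, 4 and 13 are highest in all 3, with 15.3 to 19.9 gene counts per spike-in count and 7775 to 8645 genes.

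Deeper libraries did not hold more genes. Over the 12 libraries, genes detected at a count of at least 1 against total count gave r = −0.554 (permutation p = 0.0619, adjusted 0.124) and rho = −0.559 (p = 0.0635, adjusted 0.127), as 1 of 4 relations of this kind. Without libraries 10 and 12, the farthest from the median depth, r was −0.387 (p = 0.269), and within the blocks of replicate numbers 1 to 5, 6 to 10 and 11 to 13 it was −0.479. The relation passed 0.05 without library 11 (r = −0.636, p = 0.0382), without library 13 (r = −0.722, p = 0.0128) or after thinning to equal depth (r = −0.674, p = 0.0187, adjusted 0.0749, and −0.498, p = 0.143, without libraries 10 and 12). It was weaker at a count of at least 5 (r = −0.363, permutation p = 0.250) and at a count of at least 50 (r = −0.277, permutation p = 0.385, with rho = −0.021). Because libraries 1, 4 and 13 form a separate cluster, the relation with gene counts per spike-in count was tested in the other 9 alone. There the number of genes at 50 or more counts at equal depth gave r = 0.951 (exact permutation p = 0.00329, adjusted 0.00987 over 3 relations) and rho = 0.717 (exact p = 0.0369, adjusted 0.111), with r = 0.880 without libraries 5 and 9 and 0.960 within the number blocks. The number of spike-in species gave r = −0.0969 (exact p = 0.809; rho = 0.127, p = 0.748), or −0.660 without libraries 5 and 9. Genes at a count of at least 1 gave r = 0.610 (exact p = 0.091; rho = 0.317, p = 0.410) and 0.0582 without those libraries. That last relation was not computed at equal depth, so threshold and depth both differ from the first.

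Genes of several cell type lists tended to rise and fall together over the libraries. The libraries are splits of 1 homogenate, so this is a description, and its cause was not tested. Purkinje genes had a mean pairwise Spearman correlation of 0.188 (percentile 100 among matched random lists, whose median was 0.0152) and granule cell genes 0.254 (99.99). Endothelial and mural genes had 0.480 (99.79), Bergmann glia genes 0.131 (99.59), microglial genes 0.205 (98.27) and red blood cell genes 0.287 (97.54), so that 6 of the 8 lists that could be evaluated lay at or above the 95th percentile. Interneuron genes (33.62) and oligodendrocyte genes (56.49) did not. Some of these rested on single libraries. Without library 13 the count was 3, with Bergmann glia at 89.96 and red blood cells at 85 and the endothelial list not evaluable; without library 9 microglia stood at 92.68 and without library 6 red blood cells at 92.02. With a filter of 10 TPM the count was 4 of 6, with microglia at 90.59 and the endothelial list again not evaluable. Without libraries 1, 4 and 13 together the count was 3 of 7, with Bergmann glia at 78.9 and red blood cells at 78.77.

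Of the functional lists, mitochondrially encoded genes moved most closely together (mean correlation 0.555, percentile 100). Calcium channel (98.34), cytoskeleton (98.03) and GABA synthesis genes (95.17) passed 95 too, but each fell below it without some library: calcium channels without 4 (89.97), 9 (89.32), 10 (84.99) or 11 (81.82), the cytoskeleton without 3 (89.96), 10 (92.34) or 13 (84.94), and GABA synthesis without 1 (92.93), 2 (93.83), 5 (86.23), 9 (90.94), 11 (92.02) or 12 (88.99). Glutamate receptors (92.88) passed without 3 (96.17), 4 (95.06), 9 (95.17) or 10 (96.3), and calcium handling (92.65) without 1 (97.94). With a filter of 10 TPM calcium channels stood at 90.74 and calcium handling at 99.03. With Pearson's r calcium channels stood at 94.99, GABA synthesis at 91.29 and glutamate receptors at 95.87. Without libraries 1, 4 and 13, chosen after seeing the data, calcium channels stood at 92.55, glutamate receptors at 97.07 and calcium handling at 95.65. The nuclear respiratory chain (81.08), heat shock (83.74), immediate early (68.77), sodium channel (29.36), potassium channel (58.07), GABA receptor (52.63), ataxia (57.12), zebrin-positive (65.11), zebrin-negative (41.36) and Y-linked lists (47.76) did not pass.

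The transcript that led each gene changed from library to library. Of 4845 genes with a mean TPM of at least 10 and 2 or more annotated transcripts, 12.5% (95% interval 11.6 to 13.4%) had the same leading transcript in all 12 libraries. The share was 5.80% from 10 to 50 TPM, 16.7% from 50 to 200, 49.9% from 200 to 1000 and 86.5% of the 52 genes at 1000 TPM or more. Pcp2 was led by 1 transcript in 8 libraries, which held 39.8 ± 8.19% of its TPM (SD, n = 12). Cacna1a was led by its most frequent transcript in 4 libraries, with 39.1 ± 42.7% of the gene's TPM, and Scn1a in 5 (37.7 ± 41.9%). With a filter of 50 TPM the share was 26.0%, and with 1 TPM 8.07%.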

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

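No test in this part was chosen after its result was seen. The features with numeric identifiers, which lie outside the gene results and enter only the total counts per library, held counts: up to 51 expected counts in library 5, and 149.48 over the 12 libraries. With no control samples, this was set against the limit that a count of 0 allows, 3 counts, which 7 libraries exceeded. The counts came from 4 of the 26248 features, and 1 of these held 93 of them. The tables do not name these features, so no source was tested.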

How the results depend on the processing

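Alternatives with libraries 1, 4 and 13 left out together, counts under 50 set to 0, a count of 50, a mean of 100 TPM or matching on TPM were chosen after seeing the data. The 8 cell type lists stayed below the Purkinje list under every alternative run, and the pairs that differed stayed between 20 and 23 of 28. Genes detected in all libraries were 2364 at 5 counts, 1704 at 1 TPM and 1613 at 50 counts (3694 to 3885 with 1 library left out). The median correlation was 0.564 with no filter, 0.451 from 10 TPM, 0.578 from 100 TPM, 0.541 as Pearson's r and 0.473 with counts under 50 as 0 (0.488 to 0.503). The half-detection level was 2.53 at 5 counts and 3.46 at 50 (0.63 to 0.73). Poisson calls were 4917 of 4933 genes after thinning to a hundredth, where fewer genes could be tested (13449 to 13836). Calls beyond the trend were 270 with scran, 0 with the robust fit, 0 without libraries 1, 4 and 13 and 11 with counts under 50 as 0 (1 to 2), and the cause was not tested. The spike-in difference was 0.070 with spike-ins scaled by their own totals, which removes the shared factor of each library, 0.071 without libraries 1, 4 and 13 and 0.50 when matched on TPM (0.14 to 0.29). Depth against detection was −0.674 after thinning, −0.363 at 5 counts and −0.277 at 50 counts (−0.722 to −0.484 with 1 library left out), and the cause was not tested. Co-varying cell type lists were 3 without libraries 1, 4 and 13 (3 to 6), with fewer samples. The share with 1 leading transcript was 26.0% from 50 TPM and 8.07% from 1 TPM (12.9 to 13.7%). Reported pairs turned in sign only where they had not passed: as CPM, which does not correct for transcript length, Scn8a against Scn1a (0.40) and Cacna1a against Cacna1g (−1.29, which passed in that direction, adjusted p = 0.00456); without libraries 1, 4 and 13, Cacna1a against Cacna1g (−0.12) and Nefm against Nefl (0.54); and with 1 library left out, Cacna1a against Cacna1g (−0.17 to 0.31) and Nefm against Nefl (−0.40 to 0.13). On depth, thinning to the shallowest library moved the half-detection level from 0.79 to 1.05 (log2 TPM), less than the SD of 1.03 between libraries.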

Other observations

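Of the tests below, the relation with replicate number, its blocks, the near-against-far comparison, the range of Malat1 against other genes and the relation within 9 libraries were chosen only after the result was seen, as were the settings with counts under 50 set to 0. Vascular genes were concentrated in 1 library. Library 13 held 81.7% of the summed TPM of the endothelial and mural list, 295 TPM against 45.1 in library 9, the next. Vtn, Ly6c1 and Rgs5 stood at 101, 99.5 and 80.9 TPM in it. Of all libraries it also had the most genes at 50 or more counts (8645). Vtn, a pericyte-enriched gene, Pecam1 and Cdh5, adhesion genes of endothelium, and Pdgfrb, the pericyte receptor, had 50 or more counts in library 13 only. The last 3 were named after their values were seen and were low even there, at 3.00, 0.74 and 2.84 TPM. Microglial genes were highest in libraries 8 (462 TPM in sum) and 9 (461), and in library 11 the list summed to 0. Clic6, of the choroid plexus list, reached 40.1 TPM in library 2. No biological explanation was tested for any pattern, since the design gives no groups.

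Libraries with nearby replicate numbers correlated more closely (rho −0.507 with the difference in number, p = 0.0011). A difference in depth between receiving libraries is argued against: genes with at least 1000 counts in 1 library and under 1% of that elsewhere had a low count more often in libraries whose numbers differed by at most 2 (26.9 ± 10.2%, SD, n = 12) than in those differing by at least 5 (6.24 ± 2.44%), and this held in 12 of 12 receiving libraries. Setting counts under 50 to 0 moved the correlation to 0.0186 (p = 0.883, permutation), consistent with a few reads or a little amplified product moving between libraries handled or sequenced side by side. The sharing broke between numbers 5 and 6 and between 10 and 11: at number differences of at most 2, it was 34.8 ± 16.4% within the blocks 1 to 5, 6 to 10 and 11 to 13 (SD, 28 ordered pairs) and 7.16 ± 5.80% across their borders (10). The order of handling is not in the labels, so this stays a hypothesis.

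Malat1 varied beyond the abundance trend in edgeR, in a test that called 3 genes falsely when no change was simulated. Exchange of reads with Gm37376 is argued against, since the CV of their sum was 1.00 times that of Malat1 alone (0.852). A larger share of the pool's RNA in some libraries was not decided by a test. Highest over lowest TPM was 10.2 for Malat1, against a median of 2.55 and a 95th percentile of 4.61 for 95 other genes of at least 1000 TPM. Malat1 was taken for its variation, so this comparison is no test of the explanation. TPM largely divides out an amount of RNA that all genes share, so such an amount alone would leave little trace in Malat1 TPM. An unequal share of nuclei may contribute, since Malat1 correlated with the share of TPM in retained-intron transcripts. The correlation was r = 0.774 (permutation p = 0.00292), rho = 0.685 (permutation p = 0.0174) and r = 0.779 within number blocks. Without libraries 1 and 4 r was 0.526 (permutation p = 0.117), so the relation rests on those libraries. This share was taken of gene TPM without Malat1 and Gm37376. The measure set beforehand was the summed TPM of retained-intron transcripts outside the Malat1 locus, and that sum was not tested.

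Gene counts per spike-in count differed 3.40-fold between libraries. Unequal spike-in volume as the whole cause is argued against at a threshold of 50 counts: at equal gene depth, libraries 1, 4 and 13 held 7601 to 8308 genes against 5270.0 to 6629 in the other 9, and within those 9 the number rose with the ratio (r = 0.951, exact permutation p = 0.00329, adjusted 0.00987; 0.960 within number blocks), although rho was 0.717 (adjusted p = 0.111). At a count of 1, without equal depth, r was 0.610 (p = 0.091, exact) and 0.0582 without libraries 5 and 9, so a part played by spike-in volume stays open. Unequal amounts of cellular RNA could contribute. The number of captured molecules per gene was estimated from the share of genes of 10 to 100 TPM that were missed, meaning under 50 counts at equal gene depth. It rose with the ratio at a log-log slope of 0.4996 ± 0.0332 (SE, n = 12), or 0.481 to 0.539 with 1 library left out and 0.611 in the 9 libraries of lower ratio. The estimate took all these genes to have 1 common rate. Over the 12 libraries the slope lay between the 0.2 and the 0.5 set beforehand as bounds against and for unequal RNA amount, so it decides neither way. Because it rests on captured molecules, it also cannot separate the amount of cellular RNA from a capture that differed for cellular RNA alone.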
